A study of Rattus norvegicus with 53 samples.

How the data were processed

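The values came from Affymetrix rat expression arrays, 1 array per culture, and the unit of the deposited table was log2 expression per probe set. The submitters' processing notes name RMA, which corrects background, normalises between arrays and summarises probes, and Partek 6.2. The version of RMA, the role of Partek and the scan dates were not given in the sources used here. RMA values compress differences near background, which understates changes of weakly expressed genes. The standard deviation of the values within an array ran from 1.81 to 2.32 and array medians ran from 5.29 to 5.62. No pair of arrays correlated above 0.999, so 0 arrays were duplicates.

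The table held 31099 probe sets, of which 57 were controls, and 31042 were tested. The array annotation gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780. A total of 20758 probe sets had a symbol found in the rat gene table, and 0 symbols needed updating. Where gene lists were used, each gene was represented by the probe set with the highest mean over the 53 arrays, which left 14217 genes. The annotation carried no coordinates, so genes are named by symbol only.

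Group means were fitted to all 53 arrays in 1 model of 8 groups with limma 3.58.1 in R 4.3.3, with moderated variances that followed a trend on mean expression. Benjamini-Hochberg adjustment was made within each comparison over the 31042 probe sets, and a probe set was called at an adjusted p under 0.05. The standard errors (SE) beside log2 differences are limma's moderated ones, and adjusted p-values of genes are limma's. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The fit was tested on simulated data of 31042 probe sets, of which 100 were changed by log2 1 and 100 by log2 2. It recovered 64% to 93% of changes of log2 1 and 95% to 100% of changes of log2 2, with 8 to 14 false calls per comparison. The simulated noise was independent between probe sets and between arrays, without any structure shared by sets of arrays. These rates therefore need not hold for the real arrays.

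The comparisons, the alternatives, the naming rule and 25 gene lists were fixed before the data were examined. The lists cover the interleukin-1 family, cytokines and chemokines, NF-kappaB targets, interferon response, MHC class II, T cells, B cells, monocytes, neutrophils, cytotoxic and natural killer cells, platelets, erythroid cells, regulatory T cells, T helper cytokines, immediate early genes, cell cycle, glycolysis and hypoxia, endoplasmic reticulum stress, heat shock and redox genes, sterol synthesis, liver X receptor and fatty acid genes, glucocorticoid targets, apoptosis, Toll-like and scavenger receptors, and the GIMAP family. In the Toll-like and scavenger receptor list the scavenger receptors Marco and Msr1 were not measured, so its results concern its other receptors and adaptors. Each list was tested against all other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. Camera with a correlation estimated from the residuals and fry were run beside it.

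Named genes followed a rule. Within each comparison the 10 largest increases and the 10 largest decreases among called genes were named, leaving out symbols of unnamed loci. From each list up to 4 called members with the largest change were eligible, or up to 2 with the smallest p where none was called. Il1b, Il1rn and Il1r2 were given in every interleukin-1 comparison. Where no probe set was called, the 3 named genes with the smallest p were given as not passing.

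The arrays fell into 2 clusters that the labels do not describe, found by Ward clustering after the values were seen. Complete linkage and k-means placed 53 of 53 arrays alike. Each comparison was therefore also fitted with the cluster as a block and within a cluster, and with the difference between the 3′ and 5′ actin probe sets, a measure of RNA integrity, as a covariate. The other alternatives were a second quantile normalisation, centring each array on its median, testing only probe sets with a mean above the median, variances without a trend, array weights, the replicate number as a block, fitting only the groups compared, an adjusted p under 0.01, an adjusted p under 0.2 with a log2 difference of at least 0.5, allogeneic serum as the reference, and leaving out each array.

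Replicate numbers were checked for pairing by correlating residuals of arrays with the same number across genes, with a minimum of 0.1 for every pair. The numbers paired the arrays in 3 comparisons, namely d60 DRlyp/lyp with d60 DR+/+ serum (lowest r 0.175), d40 serum of IL-1RA-treated with PBS-treated rats (lowest r 0.401), and d40 PBS serum with autologous serum (lowest r 0.153). They did not by this rule in the other 5, where the lowest r was -0.342, -0.158, -0.550, -0.484 and 0.0706. The last of these, IL-1RA in culture, had a mean r of 0.384 against -0.124 for other numbers. The first paired comparison also had a mean r of 0.384, so pairing in the IL-1RA cultures stays open. For d60 or IL-1B arrays against autologous serum the numbers matched arrays of different clusters. A pairing with autologous arrays of their own cluster, which carry other numbers, was not checked. It stays open, and the fits within that cluster ignore it. The labels do not say that numbers mark pairs, so the unpaired fit was kept and the paired counts are given with the alternatives. The number of arrays, 4 to 15 per group, limits the precision of every value.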

Results

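Expression was measured in peripheral blood mononuclear cells (PBMCs) of healthy BN (Brown Norway) rats, 180 days old, after 6 h of culture with 20% plasma or serum from different donors. PBMCs are the lymphocytes and monocytes of blood, and here they served as a sensor of what circulated in the donor rat. The donors included 2 related lines of the BioBreeding (BB) rat, DRlyp/lyp rats, which are lymphopenic and develop autoimmune diabetes, and DR+/+ rats, which do not. The 53 arrays formed 8 groups. There were 10 arrays with autologous BN serum, 15 with allogeneic BN serum (from other BN rats), 4 with autologous BN serum plus interleukin-1B (IL-1B), 4 with d60 DRlyp/lyp serum, 4 with d60 DRlyp/lyp serum plus the interleukin-1 receptor antagonist IL-1RA, and 4 with d60 DR+/+ serum. Another 6 arrays had serum of d40 DRlyp/lyp rats that had received IL-1RA from day 30 for 10 days at 350 ug/kg/day, and 6 had serum of d40 DRlyp/lyp rats that had received PBS. For the d40 IL-1RA arrays the descriptions disagree, since the sample labels say that IL-1RA was added to the serum while the study design says that the rats were treated. The design was followed here, and every d40 IL-1RA result depends on that reading. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure only the spread between samples. The number of arrays limits the precision of all values.

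The arrays split into 2 clusters that divided only the autologous and allogeneic BN groups. Serum of d40 and of d60 rats never shared a cluster, so donor age cannot be told apart from the cluster. The first principal component held 49.9% of the variance and the second 9.64%. The first cluster held 21 arrays, namely the 12 with d40 serum, 6 with autologous serum (replicates 1 to 6) and 3 with allogeneic serum (replicates 1 to 3). The second held 32 arrays, namely all with d60 serum or IL-1B, 4 with autologous serum and 12 with allogeneic serum. Between autologous arrays of the clusters alone, 17058 probe sets differed, 6036 higher and 11022 lower in the first. The log2 difference between 3′ and 5′ actin probe sets, which rises as RNA degrades, averaged 3.58 (SD 0.759, n = 21) in the first cluster and 2.58 (SD 0.402, n = 32) in the second. It ran from 0.762 in allogeneic replicate 2 to 4.31. Values with the cluster as a block, or within a cluster, therefore stand beside the pooled values of each comparison.

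**Figure D1:**
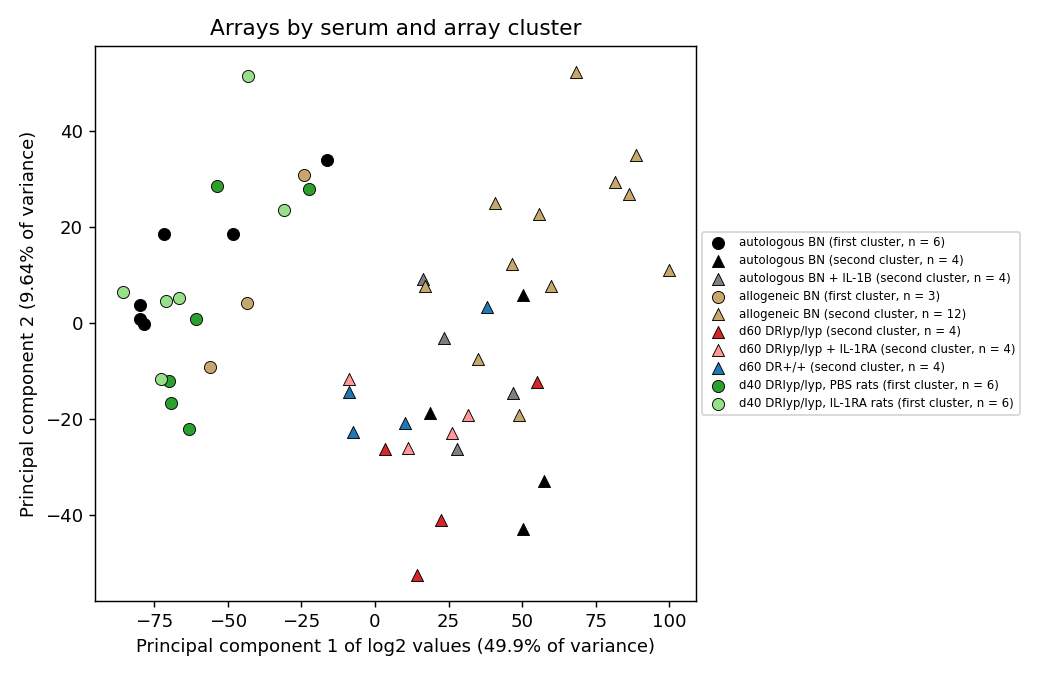
Each point is 1 of the 53 arrays, placed by its first principal component (49.9% of the variance) and second principal component (9.64%), with colour for the serum and shape for the array cluster. The 21 arrays of the first cluster lie apart from the 32 of the second along the first component, and autologous and allogeneic BN serum occur in both.

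Serum of d60 DRlyp/lyp rats was compared with autologous serum to find the genes that serum from rats near the age of diabetes onset induced in healthy cells. Redox enzymes and a chemokine rose most. Akr1b8, an aldo-keto reductase, rose by log2 2.99 (7.97-fold, SE 0.371, adjusted p = 3.4e-06), from 5.64 ± 0.730 (SD, n = 10) to 8.63 ± 0.438 (SD, n = 4). Ccl2, which attracts monocytes, rose by log2 2.65 (6.27-fold, SE 0.379, adjusted p = 5.79e-05), from 4.83 ± 0.814 to 7.48 ± 0.540. Nqo1, a quinone reductase under NRF2 control, rose by log2 2.16 (SE 0.315, adjusted p = 6.43e-05), from 6.13 ± 0.627 to 8.29 ± 0.169, and Hmox1, heme oxygenase, rose by log2 1.82 (SE 0.267, adjusted p = 6.43e-05), from 5.23 ± 0.587 to 7.05 ± 0.318. Dab2, an endocytic adaptor, rose by log2 1.67 (SE 0.276, adjusted p = 0.000697). These 5 genes stayed past the threshold in each of the 14 fits that left out 1 array and under every other alternative that could be run for them. Within the second cluster their log2 differences were 2.74 (adjusted p = 0.00175), 2.20 (0.0322), 1.76 (0.0385), 1.32 (0.0263) and 1.14 (0.0263), and with the cluster as a block 2.90, 2.28, 1.86, 1.29 and 1.00.

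Other genes rose with d60 DRlyp/lyp serum in the pooled arrays. Vcan, the proteoglycan versican, was higher by log2 2.08 (SE 0.370, adjusted p = 0.00196), Tnfsf13, the B-cell factor APRIL, by 1.98 (SE 0.387, adjusted p = 0.00907), Tgfbi by 1.96 (SE 0.428, adjusted p = 0.0320), Cd14, the lipopolysaccharide co-receptor, by 1.64 (SE 0.361, adjusted p = 0.0320) and Clec12a, an inhibitory myeloid lectin, by 1.48 (SE 0.262, adjusted p = 0.0019). Xk, which pairs with the Kell protein of red cells, fell by log2 0.83 (SE 0.193, adjusted p = 0.0491). With the cluster as a block these 6 no longer passed, at log2 1.71, 1.35, 1.63, 1.66, 1.11 and -0.73 with adjusted p from 0.0934 to 0.251. Tnfsf13 also lost its call without DRlyp/lyp replicate 3 (adjusted p = 0.109), while Tgfbi, Cd14 and Xk lost theirs in 8, 7 and 8 of 14 such fits.

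**Figure D2:**
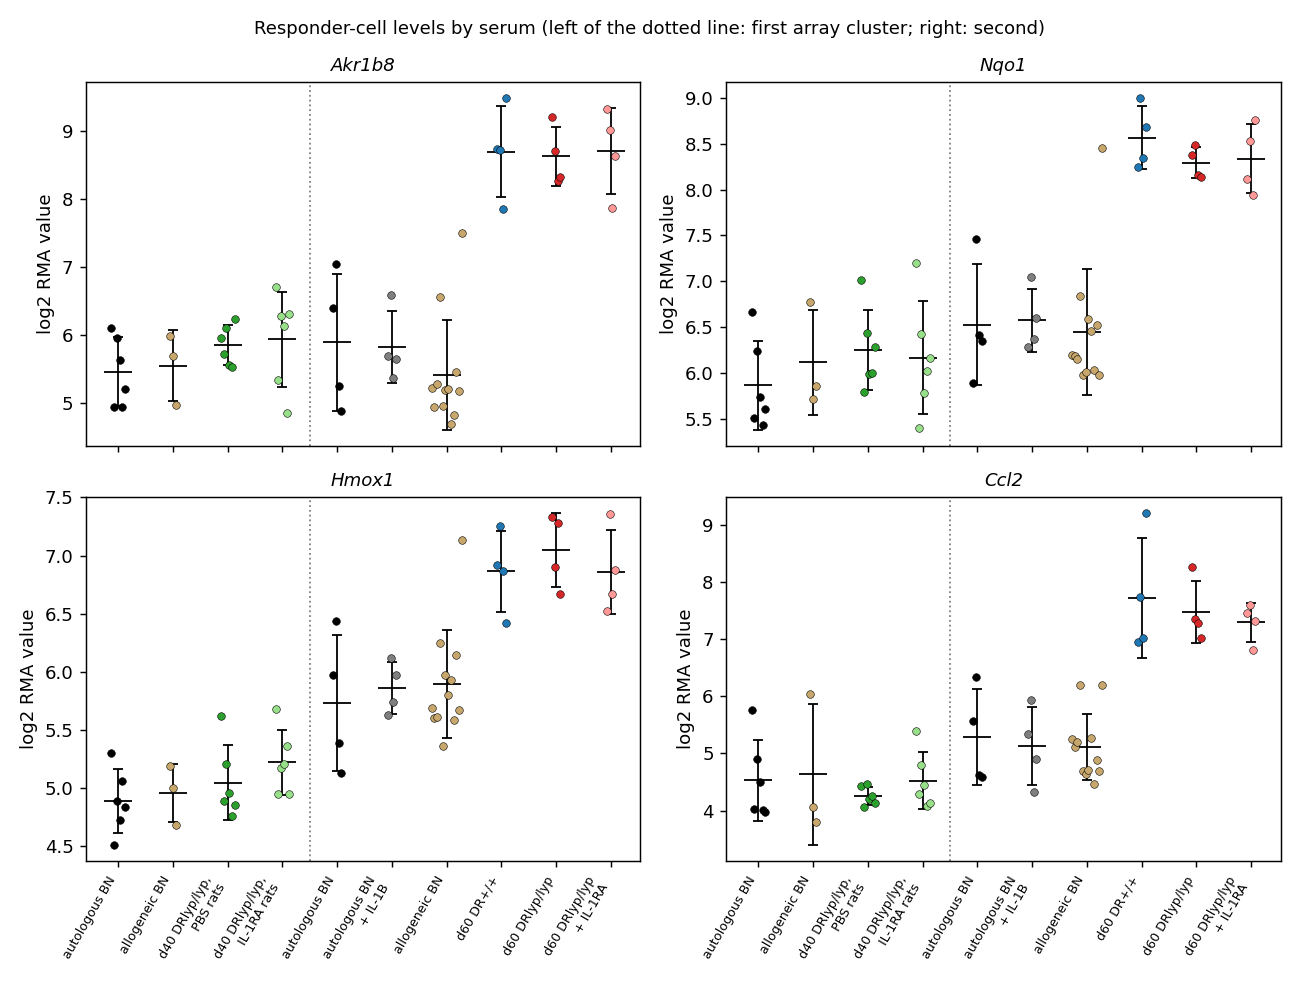
The 4 panels show log2 RMA expression of Akr1b8, Nqo1, Hmox1 and Ccl2 on each array by serum, with the first array cluster left of the dotted line, the second right of it, and bars for mean ± SD. Akr1b8 averaged 8.63 with d60 DRlyp/lyp serum and 8.70 with d60 DR+/+ serum, against 5.64 over the 10 arrays with autologous serum.

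Among the gene lists, heat shock and redox genes were higher with d60 DRlyp/lyp serum. Of 14 measured members 3 rose over all genes tested and 5 adjusted over the list alone, the third being Slc7a11, a cystine transporter, at log2 1.31 (adjusted p = 0.0321). The list's median was 0.39 (camera adjusted p = 4.56e-05, and adjusted p = 0.0633 with an estimated correlation), 0.24 with the block and 0.19 within the second cluster. Monocyte genes had 3 of 22 members up (11 adjusted over the list alone) with a median of 0.60 (adjusted p = 6.05e-08, and adjusted p = 0.232 with an estimated correlation), among them Cd68 at 1.14, a macrophage glycoprotein, but 0 with the block, where the median was 0.29. The Toll-like and scavenger list, without Marco and Msr1, had 1 of 17 up, Cd14 (6 adjusted over the list alone). Its median was 0.60 (camera adjusted p = 0.00201, and adjusted p = 0.232 with an estimated correlation). Cytokines and chemokines had 3 of 27 up (7 adjusted over the list alone), namely Ccl2, Ccl3 at 0.96 and Il6 at 0.46, with a median of 0.34 (adjusted p = 4.7e-06, and adjusted p = 0.232 with an estimated correlation). That median was -0.04 within the second cluster (adjusted p = 0.779), where Ccl2 alone stayed up. Ccl3 lost its call in 8 of 14 fits without 1 array, Slc7a11 in 9, and Il6 and Cd68 in 3 each, with the highest adjusted p of 0.319, 0.187, 0.270 and 0.109.

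In other lists few members passed with d60 DRlyp/lyp serum. MHC class II genes had 0 of 13 called (6 up adjusted over the list alone, median 0.51, adjusted p = 0.000288, and adjusted p = 0.232 with an estimated correlation), and cytotoxic and natural killer genes 0 of 20 (5 adjusted over the list alone, median 0.44, adjusted p = 4.56e-05, and adjusted p = 0.232 with an estimated correlation). The platelet list, 13 genes of a blood cell other than PBMCs, had 0 called and a median of -0.40 (adjusted p = 0.000131, and adjusted p = 0.232 with an estimated correlation), and -0.67 within the second cluster. The erythroid list, also of another blood cell, had 0 of 9 called (3 up adjusted over the list alone) and a median of 0.91 (adjusted p = 0.00633, and adjusted p = 0.414 with an estimated correlation), which was -0.02 within the second cluster. Cell cycle genes had 1 of 27 up, the inhibitor Cdkn1a at 0.85 (1 adjusted over the list alone, median 0.31, adjusted p = 0.00251, and adjusted p = 0.292 with an estimated correlation). Apoptosis genes had 0 of 15 called (3 down adjusted over the list alone, median -0.19, adjusted p = 0.00201, and adjusted p = 0.232 with an estimated correlation). T-cell genes had a median of -0.13 (adjusted p = 0.0228, and adjusted p = 0.564 with an estimated correlation) and glucocorticoid targets one of -0.10 (adjusted p = 0.0496, and adjusted p = 0.232 with an estimated correlation), each with 0 called. Both T-cell and apoptosis medians turned positive within the second cluster, at 0.14 and 0.02.

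Several lists did not pass as a group, though 3 of them held a gene that rose. NF-kappaB targets had 1 of 23 up, Plaur at 0.82, the urokinase receptor (median 0.13, adjusted p = 0.386), glycolysis and hypoxia genes 1 of 23, the vessel growth factor Vegfa at 1.04 (median 0.07), and liver X receptor genes 1 of 19, Nr1h3 at 0.80, the receptor itself (median 0.31, adjusted p = 0.0851). Adjusted over the list alone these lists had 3, 1 and 3 members up. Endoplasmic reticulum stress genes had 0 called (4 adjusted over the list alone, median 0.17, adjusted p = 0.132). With 0 members called and no call as a list, medians were 0.18 for the interleukin-1 family (adjusted p = 0.644), 0.12 for interferon response (0.386), 0.24 for B cells (0.220), 0.18 for neutrophils (0.356), 0.10 for T helper cytokines (0.866), -0.01 for immediate early genes (0.0621), 0.14 for sterol synthesis (0.671) and -0.19 for the 5 GIMAP genes (0.391). Regulatory T-cell genes had a median of 0.18 and a mean of 0.02 while the test pointed down (adjusted p = 0.891). Plaur, Cdkn1a, Vegfa and Nr1h3 lost their calls in 8, 9, 6 and 8 of the 14 fits without 1 array, with the highest adjusted p of 0.249, 0.187, 0.150 and 0.118.

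In all, limma called 51 probe sets between d60 DRlyp/lyp and autologous serum, 45 higher and 6 lower, which covered 29 genes higher and 1 lower. With the cluster as a block 9 were called, all higher, and within the second cluster, with 4 autologous arrays, 11 were called, 10 higher and 1 lower. The count hung on single arrays. It was 16, 29, 21 and 26 without DRlyp/lyp replicates 1, 2, 3 and 4, it was 24, 32, 27, 27 and 24 without autologous replicates 2, 3, 4, 5 and 6, and it was 396, 740, 389 and 214 without autologous replicates 7, 8, 9 and 10, which are those of the second cluster.

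Serum of d60 DR+/+ rats, which share the BB background without lymphopenia, was compared with autologous serum in the same way. Akr1b8, Ccl2 and Nqo1 again rose most. Akr1b8 rose by log2 3.07 (8.38-fold, SE 0.371, adjusted p = 1.7e-06) to 8.70 ± 0.666 (SD, n = 4), Ccl2 by 2.90 (SE 0.379, adjusted p = 4.01e-06) to 7.73 ± 1.05, Nqo1 by 2.43 (SE 0.315, adjusted p = 3.99e-06) to 8.57 ± 0.340, and Hmox1 by 1.64 (SE 0.267, adjusted p = 0.000322) to 6.86 ± 0.345. Fn1, fibronectin, rose by 2.42 (SE 0.413, adjusted p = 0.000633) from 7.80 ± 0.687 (n = 10) to 10.22 ± 0.731 (n = 4), and Mpeg1, a pore-forming protein of macrophages, by 2.15 (SE 0.344, adjusted p = 0.000244). Vcan rose by 2.13 (adjusted p = 0.000797) and Dab2 by 1.78 (adjusted p = 0.000134). These 8 genes passed in each fit without 1 array and under every other alternative run for them, and within the second cluster they stood at 2.81, 2.45, 2.04, 1.13, 2.63, 2.23, 1.79 and 1.25. Tgfbi rose by 2.17 (adjusted p = 0.00473; 0.0583 without DR+/+ replicate 2) and Tnfsf13 by 2.03 (adjusted p = 0.00307, but 0.0658 within the second cluster at 1.39 and 0.0992 in a fit of the 2 groups alone).

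Decreases with d60 DR+/+ serum were led by Rasd1, a dexamethasone-inducible Ras-like protein, which fell by log2 1.80 (SE 0.324, adjusted p = 0.0014) from 8.25 ± 0.720 (n = 10) to 6.45 ± 0.551 (n = 4). It fell by 2.27 with the cluster as a block and by 2.10 within the second cluster (adjusted p = 0.000803). It did not pass in fits of the 2 groups alone, unpaired (adjusted p = 0.138) or with replicate numbers as a block (-1.47, adjusted p = 0.0850). Asap2 fell by 1.46 (adjusted p = 0.0466), but stood at -0.90 with the block (adjusted p = 0.129). Atp8a1, a phospholipid flippase, fell by 1.03 (adjusted p = 0.00249, or 0.119 without DR+/+ replicate 4), although 1 of its 2 other probe sets was at 0.08. Marchf8, a ubiquitin ligase that acts on MHC class II, fell by 0.82 (adjusted p = 0.0431) and Tex2 by 0.75 (adjusted p = 0.0446). Asap2, Marchf8 and Tex2 lost their calls in 11, 10 and 10 of the 14 fits without 1 array, the highest adjusted p being 0.207, 0.511 and 0.260.

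Members of the redox, monocyte and pattern receptor lists rose with d60 DR+/+ serum. Heat shock and redox genes had 3 of 14 up (5 adjusted over the list alone), namely Nqo1, Hmox1 and Slc7a11 at 1.24, with a median of 0.44 (adjusted p = 5.91e-07, and adjusted p = 0.0106 with an estimated correlation), and 0.17 within the second cluster (adjusted p = 0.00276). Monocyte genes had 4 of 22 up (13 adjusted over the list alone) with a median of 0.48 (adjusted p = 1.78e-12, and adjusted p = 0.0512 with an estimated correlation) and 0.32 within the second cluster. Its members included Cd14 at 1.61, Csf1r at 1.28, the receptor for macrophage growth factor, and Cd68 at 1.12. The Toll-like and scavenger list had 2 of 17 up (9 adjusted over the list alone), Cd14 and the inhibitory Fc receptor Fcgr2b at 1.28. Its median was 0.54 (camera adjusted p = 2.14e-07, and adjusted p = 0.0495 with an estimated correlation) and 0.41 within the second cluster. MHC class II genes had 1 of 13 up (2 adjusted over the list alone), the class II transactivator Ciita at 1.12 (adjusted p = 0.00191; 0.0202 within the second cluster), with a median of 0.23 (adjusted p = 0.000934, and adjusted p = 0.276 with an estimated correlation). Ciita did not pass in fits of the 2 groups alone, unpaired (adjusted p = 0.119) or with replicate numbers as a block (adjusted p = 0.0683). Calls were lost without 1 array for Cd14 (without DR+/+ replicates 2 or 3 or autologous replicate 2), Cd68 (DR+/+ replicates 2 or 4) and Fcgr2b (DR+/+ replicates 2 or 4 or autologous replicate 5), at adjusted p up to 0.151, 0.126 and 0.369. They were lost for Csf1r in 10 and Slc7a11 in 8 of the 14 fits, at adjusted p up to 0.260 and 0.573.

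The platelet list moved the other way with d60 DR+/+ serum. It had 0 of 13 called (4 down adjusted over the list alone) and a median of -0.77 (adjusted p = 7.8e-10, and adjusted p = 0.0600 with an estimated correlation). With the cluster as a block 4 members were down and the median was -1.11, and within the second cluster 2 were down, Mmrn1 at -1.52 (adjusted p = 0.0141), a multimerin of platelet granules, and Gp5 at -1.22 (adjusted p = 0.0368), a platelet glycoprotein, with a median of -0.94 (adjusted p = 3.37e-05, and adjusted p = 0.354 with an estimated correlation). Vwf, von Willebrand factor, was at -1.43 in the pooled fit and did not pass (adjusted p = 0.0727). Glucocorticoid targets had 0 of 14 called and a median of -0.43 (adjusted p = 0.00142, and adjusted p = 0.0495 with an estimated correlation), but -0.20 with the block (adjusted p = 0.279).

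Other lists with d60 DR+/+ serum held 0 to 2 called members. Cytokines had 1 of 27 up, Ccl2 (4 adjusted over the list alone, median 0.18, adjusted p = 4.9e-05, and adjusted p = 0.436 with an estimated correlation), with a median of -0.13 within the second cluster. Liver X receptor genes had 2 of 19 up (3 adjusted over the list alone), the cholesterol exporter Abca1 at 0.88 and the lipid carrier Fabp5 at 1.39, with a median of 0.14 (adjusted p = 0.0269, and adjusted p = 0.0721 with an estimated correlation). B-cell genes had 1 of 14 up, Fcer2 at 0.96, the low-affinity IgE receptor (2 adjusted over the list alone, median 0.18, adjusted p = 0.0101, and adjusted p = 0.436 with an estimated correlation). Cell cycle genes had 1 of 27 up, Cdkn1a at 0.77 (2 adjusted over the list alone, median 0.26, adjusted p = 0.0191, and adjusted p = 0.461 with an estimated correlation). T-cell genes had 0 called and a median of -0.24 (adjusted p = 0.00173, and adjusted p = 0.436 with an estimated correlation), and erythroid genes 0 of 9 with a median of 1.01 (adjusted p = 0.00556, and adjusted p = 0.436 with an estimated correlation) that was -0.24 within the second cluster. No call as a list was made for immediate early genes, with 1 of 23 up, the transcription factor Klf4 at 1.25 (1 adjusted over the list alone, median 0.10, adjusted p = 0.470), for endoplasmic reticulum stress genes, with Chac1 at 0.91, an enzyme that degrades glutathione (4 up and 1 down adjusted over the list alone, median 0.09, adjusted p = 0.248), or for glycolysis and hypoxia genes, with Vegfa at 0.98 (1 adjusted over the list alone, median -0.11). Chac1 did not pass in fits of the 2 groups alone, unpaired (adjusted p = 0.260) or with replicate numbers as a block (adjusted p = 0.0663). With 0 called, medians were 0.13 for the interleukin-1 family, 0.00 for NF-kappaB targets, where Bcl2a1 at 1.08 did not pass (adjusted p = 0.0581), 0.11 for interferon response, 0.17 for neutrophils, 0.11 for cytotoxic genes, -0.02 for T helper cytokines, 0.19 for sterol synthesis, -0.08 for apoptosis and -0.12 for GIMAP genes. Regulatory T-cell genes had a median of 0.06 and a mean of -0.03. Calls were lost without 1 array for Abca1 (DR+/+ replicate 4), Fabp5 and Klf4 (DR+/+ replicates 2 or 4), Fcer2 (DR+/+ replicates 1 or 4), Cdkn1a (10 of 14 fits) and Vegfa (5 of 14 fits), at adjusted p up to 0.290, 0.177, 0.303, 0.419, 0.186 and 0.296.

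Between d60 DR+/+ and autologous serum limma called 93 probe sets, 86 higher and 7 lower, which covered 53 genes higher and 5 lower. With the cluster as a block 987 were called, 737 higher and 250 lower, and within the second cluster 418, 301 higher and 117 lower. The pooled count was 44 without DR+/+ replicate 4, whose actin difference of 1.13 was the lowest of its group, and 58, 61 and 60 without autologous replicates 2, 5 and 6.

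DRlyp/lyp and DR+/+ serum were compared directly to find effects of the lymphopenia genotype apart from the shared BB background. No gene passed the test. Rasd1 was closest, at 8.24 ± 0.126 (SD, n = 4) with DRlyp/lyp and 6.45 ± 0.551 (SD, n = 4) with DR+/+ serum, a log2 difference of 1.78 (SE 0.387, limma adjusted p = 0.850, and 0.118 within the second cluster). Gtpbp3 at -0.54 and Pakap at -1.03 followed, the latter with 1 of 3 other probe sets of opposite sign. Cytotoxic and natural killer genes were higher as a list with DRlyp/lyp serum, with 17 of 20 members above 0, a median of 0.38 and 0 called (1 up adjusted over the list alone, adjusted p = 0.000148, and adjusted p = 0.945 with an estimated correlation). Among them the lectin receptor Klrb1b was at 0.94 (SE 0.282) and the death ligand Faslg at 0.47, neither of which passed. Immediate early genes were lower, with a median of -0.11, a mean of -0.22 and 0 of 23 called (adjusted p = 0.00486, and adjusted p = 0.182 with an estimated correlation), where Klf2 at -0.99 and Klf4 at -0.87 did not pass. In the other 23 lists no member was called and the adjusted p was at least 0.338. By limma 0 of 31042 probe sets were called, with 946 at an unadjusted p under 0.05 where chance gives 1552, 0 with the cluster as a block (1811 unadjusted) and 0 within the second cluster (1864 unadjusted). The 45 and 86 probe sets higher with DRlyp/lyp and DR+/+ serum shared 29, but both sets were called against the same autologous arrays, and the overlap those alone would give was not tested. The log2 differences of the pair of comparisons correlated across probe sets at r = 0.753, but they share the autologous arrays, and arrays with the same replicate number correlate in their residuals (mean r 0.384). Simulated data with no effect gave r = 0.286 from the shared arrays and 0.559 with that pairing added, without the cluster difference that the pooled comparisons also share. Within the second cluster r was 0.694, against 0.693 simulated with pairing (0.501 without it), so the value within the cluster does not show a shared response. Why the pooled value exceeds its simulated one was not tested. With the autologous arrays divided between the comparisons r was 0.431 and 0.400, against 0.127 simulated with pairing. Each part held autologous arrays of both clusters while the d60 arrays were all of the second, so both comparisons carried the cluster difference. The simulation lacked it, so these values do not show a shared response either. A shift common to all autologous arrays was not simulated, and probe sets are not independent replicates.

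Allogeneic BN serum was compared with autologous BN serum to measure the effect of serum from another healthy rat of the same strain. In the pooled arrays many genes moved modestly. Tmc4 was higher by log2 1.39 (SE 0.347, adjusted p = 0.00613), at 8.82 ± 1.17 (SD, n = 15) against 7.43 ± 1.09 (SD, n = 10). Hemgn, a nuclear protein of blood progenitors, was higher by 1.17, Adam22 by 1.12, the glutamate receptor Grm8 by 1.09, Rrp12 by 1.06, the ubiquitin enzyme Ube2c by 1.03, Nenf by 1.01, the red cell protein Tmod1 by 1.00, Hsd3b7 by 0.99 and the Kell antigen Kel by 0.91. Nfkb2, a subunit of NF-kappaB, was lower by 1.36 (SE 0.290, adjusted p = 0.00516), Tmed5 by 1.46 (SE 0.387, adjusted p = 0.0073), Hivep1 by 1.44, the autophagy regulator Ambra1 by 1.43, Pgpep1 by 1.42, the actin regulator Wasf2 by 1.42, Klf13 by 1.34, the helicase Ddx39b by 1.33, Srp9 by 1.32 and Ubn1 by 1.32. None of these 20 passed with the cluster as a block, where Tmc4 was at 0.57 (adjusted p = 0.254), Tmed5 at -1.17 (adjusted p = 0.199) and Nfkb2 at -1.14 (adjusted p = 0.160). Within the second cluster Rrp12 and Kel turned to -0.40 and -0.10, and Wasf2, Klf13 and Ubn1 to 0.02, 0.06 and 0.25, while Grm8 was at -0.03 in the first. In the first cluster Wasf2 passed at -2.50 (adjusted p = 0.00418), while Klf13 at -1.36 and Ubn1 at -1.13 did not pass. Hemgn, Rrp12, Ube2c, Tmod1 and Kel lost their calls in 6, 11, 5, 5 and 6 of the 25 fits without 1 array, at adjusted p up to 0.111, 0.108, 0.0671, 0.0686 and 0.103.

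Pooled over clusters, cytokine genes were higher with allogeneic serum, with 7 of 27 up (7 adjusted over the list alone, median 0.24, adjusted p = 0.00776, and adjusted p = 0.683 with an estimated correlation), among them Csf1 at 0.81, Lif at 0.53, Nos2 at 0.50 and Ccl7 at 0.41. T-cell genes were lower, with 9 of 20 down (11 down and 1 up adjusted over the list alone, median -0.46, adjusted p = 0.0199, and adjusted p = 0.683 with an estimated correlation), including the transcription factors Tcf7 at -1.31 and Lef1 at -1.15. Apoptosis genes were lower, with 8 of 15 down (9 adjusted over the list alone, median -0.45, adjusted p = 0.0282, and adjusted p = 0.683 with an estimated correlation), including Birc2 at -0.97 and Casp8 at -0.87. The remaining lists were not called. NF-kappaB targets had 3 up and 9 down (median -0.30, adjusted p = 0.0560), with the inhibitor Nfkbia at -1.12 and Relb at -0.94, and endoplasmic reticulum stress genes 1 up and 7 down (median -0.31, adjusted p = 0.0560), with the chaperone Hspa5 at -1.02. Immediate early genes had 4 up and 5 down, with Klf2 at -1.27 and Zfp36 at -0.84. GIMAP genes had 3 of 5 down, including Gimap5 at -0.88, the gene altered in DRlyp/lyp rats (median -0.86, adjusted p = 0.141), and erythroid genes 4 of 9 up (median 0.57, adjusted p = 0.125). Interferon response had 4 up and 10 down with Irf1 at -1.14, the interleukin-1 family 4 up and 6 down with Pycard at -0.89, and sterol synthesis 1 up and 6 down. MHC class II had 2 down, with Cd74 at -0.60, platelets 2 down, B cells 3 down, monocytes 4 up and 1 down, neutrophils 3 up and cytotoxic genes 1 up. Regulatory T cells had 2 up and 4 down, T helper cytokines 3 up and 2 down, cell cycle 4 up and 7 down, glycolysis and hypoxia 1 up and 5 down, heat shock and redox 3 up and 1 down, liver X receptor genes 3 up and 3 down, glucocorticoid targets 1 up and 3 down, and pattern receptors 1 down. Adjusted over the list alone these counts were the same except for B cells (0), monocytes (4 up, 0 down), cytotoxic genes (0), platelets (1 down), glucocorticoid targets (0) and pattern receptors (0). With the cluster as a block 0 members were called in any list.

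In all, limma called 12614 probe sets between allogeneic and autologous serum, 7223 higher and 5391 lower. With the cluster as a block 0 were called (smallest adjusted p = 0.0863), with 5242 at an unadjusted p under 0.05. In the first cluster allogeneic replicates 2 and 3 had 3′ to 5′ actin differences of 0.762 and 2.81, against 3.20 to 4.31 in the autologous arrays. Within the first cluster (3 against 6 arrays) 332 were called, 36 higher and 296 lower, and within the second (12 against 4) 3 were, all lower. The named genes among these 3, chosen after their values were seen, were Imp3 at -1.08 (adjusted p = 0.0171) and Ins2, an insulin gene, at -1.05 (adjusted p = 0.0231). The pooled count was 7303, 7495 and 7396 without autologous replicates 2, 3 and 6.

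IL-1B was added to autologous serum to induce genes that respond to interleukin-1. No gene passed the test. Il1b itself was at 8.69 ± 0.261 (SD, n = 4) with IL-1B and 8.78 ± 1.31 (SD, n = 10) without, a log2 difference of -0.09 (SE 0.609, limma adjusted p = 0.946). Il1rn, which encodes IL-1RA, differed by 0.23 (SE 0.163, limma adjusted p = 0.469) and the decoy receptor Il1r2 by 0.36 (SE 0.844, limma adjusted p = 0.827). The smallest p-values were those of Zfp267 at -0.84, Actn3 at 0.44 and Rai14 at 0.38, each at adjusted p = 0.393. The interleukin-1 family had 0 of 20 called and a median of 0.01 (adjusted p = 0.970). Cytokines with 0 of 27 called and a median of 0.25 (adjusted p = 0.0029), T-cell genes with 0 of 20 and a median of -0.30 (adjusted p = 0.0029) and erythroid genes with 0 of 9 (3 up adjusted over the list alone) and a median of 0.90 (adjusted p = 0.00215) were called as lists, each at adjusted p = 0.982 with an estimated correlation. Their medians with the cluster as a block were -0.07, 0.01 and 0.13. By limma 0 probe sets were called, with 3932 at an unadjusted p under 0.05, 0 with the block (898 unadjusted) and 0 within the second cluster (1121 unadjusted). The genes higher with IL-1B were to be followed into the other interleukin-1 comparisons, but that set held 0 genes and could not be tested.

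IL-1RA was added to d60 DRlyp/lyp serum to block effects of interleukin-1. No gene passed the test. Il1b was at 9.66 ± 0.337 (SD, n = 4) with IL-1RA and 9.49 ± 0.429 (SD, n = 4) without, a log2 difference of 0.17 (SE 0.728), Il1rn differed by -0.03 (SE 0.195) and Il1r2 by -0.05 (SE 1.01). Ankrd37 at -0.50, Rpain at -0.71 and Zfp777 at 0.75 had the smallest p and did not pass. Immediate early genes were higher as a list, with 21 of 23 above 0, a median of 0.11 and 0 called (adjusted p = 0.00725, and adjusted p = 0.227 with an estimated correlation). Apoptosis genes had a median of 0.19 with 0 called (adjusted p = 0.00725, and adjusted p = 0.637 with an estimated correlation) and cytotoxic genes one of -0.19 with 0 called (adjusted p = 0.0199, and adjusted p = 0.982 with an estimated correlation). The other 22 lists had adjusted p of at least 0.188. By limma 0 probe sets were called, with 519 at an unadjusted p under 0.05, 0 with the cluster as a block (909 unadjusted) and 0 within the second cluster (956 unadjusted).

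Serum of d40 DRlyp/lyp rats treated with IL-1RA was compared with serum of PBS-treated rats to see whether treatment of the animal changed what its serum induced, with the d40 arrays read by the study design rather than by their labels. No gene passed in the pooled fit. Olfm1, a secreted olfactomedin, had the smallest p, at 7.65 ± 0.369 (SD, n = 6) against 6.30 ± 0.534 (SD, n = 6), a log2 difference of 1.36 (SE 0.337), and it passed with the cluster as a block (limma adjusted p = 0.00056), within the first cluster (limma adjusted p = 0.000564) and with replicate numbers as a block in the 12 arrays (limma adjusted p = 0.0121). Rasa2 at 0.74 and Reep6 at -0.85 did not pass. Il1b differed by -0.34 (SE 0.594), Il1rn by -0.01 (SE 0.159) and Il1r2 by 0.41 (SE 0.824). MHC class II genes were lower as a list, with a median of -0.25 and 0 of 13 called (adjusted p = 3.19e-05, and adjusted p = 0.181 with an estimated correlation), and 2 members, Ciita at -0.58 and RT1-DMb at -0.50, were down adjusted over the list alone with the cluster as a block. B-cell genes were lower at a median of -0.23 (adjusted p = 0.00741, and adjusted p = 0.514 with an estimated correlation). Immediate early genes (median 0.06, adjusted p = 0.0013), glucocorticoid targets (median 0.12, adjusted p = 0.00863) and T helper cytokines (median 0.02, adjusted p = 0.0411) were higher, with 0 members called and an adjusted p = 0.0892, 0.154 and 0.181 with an estimated correlation. By limma 0 probe sets were called, with 318 at an unadjusted p under 0.05, and 1, Olfm1, was called with the cluster as a block and within the first cluster. With replicate numbers as a block in the 12 arrays, which the numbers pair, 3 were called. They were Olfm1, Rasd1 at 0.74 (limma adjusted p = 0.0249) and 1 unnamed.

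The 29 genes higher with d60 DRlyp/lyp serum were followed into the d40 treatment comparison, which shares no array with the first. Their median log2 difference between serum of IL-1RA-treated and PBS-treated rats was -0.01, with 14 of 29 above 0. Camera pointed up, against the sign of the median (p = 0.085, p = 0.553 with an estimated correlation), and fry gave p = 0.930. The lower set held 1 gene, Xk, and was not tested.

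Serum of d40 PBS-treated DRlyp/lyp rats was compared with autologous serum as the untreated reference at that age. No gene passed the test. Eaf2 was at 4.02 ± 0.296 (SD, n = 6) against 5.13 ± 0.616 (SD, n = 10), a log2 difference of -1.11 (SE 0.221, limma adjusted p = 0.209), Dxo was at 0.52 (adjusted p = 0.542) and Ciita at 0.71 (SE 0.180, limma adjusted p = 0.542). Pooled, cytokines (median -0.19, 0 of 27 above 0, adjusted p = 0.00175), platelet genes (-0.38, adjusted p = 0.0184) and erythroid genes (-0.52, adjusted p = 0.0152) were lower as lists and T-cell genes (0.32, adjusted p = 0.00694) and apoptosis genes (0.26, 1 adjusted over the list alone, adjusted p = 0.0202) higher, with 0 members called and each at adjusted p = 0.745 with an estimated correlation. With replicate numbers as a block, which pair these arrays, the T-cell list (adjusted p = 0.00183) and the platelet list (adjusted p = 0.000118) kept their calls, and the cytokine (adjusted p = 0.0651), erythroid (adjusted p = 0.134) and apoptosis lists (adjusted p = 0.253) lost theirs. Within the first cluster the cytokine and erythroid medians were 0.02 and 0.03, while platelet genes were at -0.25 (adjusted p = 0.00034, and adjusted p = 0.427 with an estimated correlation) and MHC class II genes at 0.26 (2 up adjusted over the list alone, adjusted p = 0.00167, and adjusted p = 0.418 with an estimated correlation). By limma 0 probe sets were called, with 2738 at an unadjusted p under 0.05, 0 with the cluster as a block (620 unadjusted) and 0 within the first cluster (1100 unadjusted), while 1 was called without autologous replicate 1. Whether the effect of DRlyp/lyp serum differed between d40 and d60, each against autologous arrays of its own cluster, was tested for each probe set and 0 differed by limma, with 1450 at an unadjusted p under 0.05. That count does not show alike effects, since the median SE of this difference was 0.229 and donor age went with the array cluster. The 29 genes higher with d60 DRlyp/lyp serum had a median of 0.145 with d40 PBS serum within the first cluster. With d60 DRlyp/lyp serum it was 0.803 within the second, on arrays that had helped to choose them.

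The effect of IL-1RA added to the culture was set against that of IL-1RA given to the rats by testing the difference of the pair of differences. If the labels of the d40 arrays are right and IL-1RA was added to the serum, both sides of this contrast are additions to culture. No gene passed. Tmem237 at -0.64, Piga at -0.88 and Zfp777 at 0.97 had the smallest p, and Il1b differed by 0.51 (SE 0.940), Il1rn by -0.02 (SE 0.252) and Il1r2 by -0.45 (SE 1.30). None of the 25 lists was called, the smallest adjusted p being 0.185 for apoptosis genes. By limma 0 probe sets were called, with 322 at an unadjusted p under 0.05, 0 with the cluster as a block (549 unadjusted) and 0 within clusters (567 unadjusted).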

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

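The test of unequal cluster shares behind the allogeneic calls was chosen after its result had been seen, and the fits within clusters and with the actin covariate after the clusters had been seen. Il1rn in d40 IL-1RA-treated rats was at log2 4.93 in replicate 1, above the 4.27 to 4.50 of the other 5 arrays. Il1rn in d40 PBS-treated rats was at 4.90 in replicate 1, above the 4.33 to 4.47 of the others. Tnfsf13 with IL-1B was at 5.14 in replicate 1, below the 6.22 to 6.27 of the other 3. Of 126 groups of values examined 3 held such a distant array, and chance flags about 1 in 20 groups, or 6.3 here. The effect of allogeneic serum differed between the clusters in 216 probe sets by a test of the difference. Its first-cluster side rests on 3 allogeneic arrays. Replicates 2 and 3 of these had 3′ to 5′ actin differences of 0.762 and 2.81, below those of the autologous arrays there (3.20 to 4.31). Among named genes the largest differences were those of Sh3bgrl1 at -3.08 (SE 0.767, limma adjusted p = 0.0425), the kinase Cdk12 at -2.75 (SE 0.538, limma adjusted p = 0.0140), which was at -2.17 in the first and 0.58 in the second, and Bod1l1 at -2.73 (SE 0.665, limma adjusted p = 0.0388). The smallest p-values among named genes were those of Ccdc71 at -1.28, Cdk12 and Inpp4b at -2.54, each at limma adjusted p = 0.0140. Over all probe sets the smallest limma adjusted p was 0.0109. All of these genes were named after their values were seen.

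Regrouping the same arrays asked whether chance could give as many calls. Chance could not be excluded for d60 DRlyp/lyp against autologous serum, where 6 of 100 splits called as many as the real 51 and the highest other called 9402, or for d60 DR+/+ against autologous serum (6 of 100, real 93, highest other 9618). The highest splits separated the array clusters, with shares of the first cluster that differed by 0.8, which points to a structure of the samples. Within the second cluster only the real split called as many for d60 DRlyp/lyp serum (1 of 35, real 11, highest other 2). That is the smallest share 35 splits can give, and several such tests were run, so chance is not excluded by it. For d60 DR+/+ serum another split called more than the real one (2 of 35, real 418, highest other 2379). That higher split set DR+/+ replicates 1, 2 and 3 with autologous replicate 9 against DR+/+ replicate 4 with autologous replicates 7, 8 and 10, again a structure of the samples. For allogeneic serum only the real split called as many (1 of 100, real 12614), but the highest other split, with 11563, also differed in cluster share, by 0.433. The splits did not hold the cluster share fixed, so they cannot tell a serum effect from the cluster difference. Where the real count was 0, every split calls at least as many by construction, so the regrouping says nothing about chance for DRlyp/lyp against DR+/+ (35 of 35, highest other 5), IL-1B (100 of 100, highest other 12221), IL-1RA in culture (35 of 35, highest other 0), d40 IL-1RA against PBS (100 of 100, highest other 31), d40 PBS against autologous serum (100 of 100, highest other 7135) and the difference between the IL-1RA comparisons (100 of 100, highest other 0). Splits that part every numbered pair gave 0 calls in each of 8, 8 and 32 for DRlyp/lyp against DR+/+, IL-1RA in culture and d40 IL-1RA against PBS.

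The calls between allogeneic and autologous serum go with the array clusters. Response to another BN rat's serum as the whole cause is argued against by the called probe sets' median log2 difference, which was 0.186 with the cluster as a block (quartiles 0.120 to 0.291) against 0.415 pooled, and 0.199 within the second cluster. Unequal cluster shares remain a candidate explanation, since the first cluster held 60% of autologous and 20% of allogeneic arrays, and 0 probe sets were called with the block. Of the 12614 called, 8534 also differed between autologous arrays of the clusters, 8518 of them toward the second. Over all 31042 probe sets 17058 differed so. Both contrasts used the same autologous arrays, which favours this overlap and its common direction, so the count is no separate support. A smaller serum effect under the cluster difference stays open, and what made the clusters is not given in the sources used here.

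For the 29 genes higher with d60 DRlyp/lyp serum, the median was 0.755 with the block (quartiles 0.577 to 1.35), against 1.04 pooled. Their median SE was 0.214 with the block against 0.222. The genes were chosen on these same arrays, which favours a median above 0, so it cannot decide whether unequal cluster shares were the whole cause. Of the 29, 6 were still called with the block over all probe sets. That argues against cluster shares as the whole cause for those 6. Why the other calls ended was not tested gene by gene. Cd14, for one, lost its call at 1.66 against 1.64 pooled, with an SE of 0.397 against 0.361. A larger share of monocytes stays open. The monocyte list had a median of 0.233 within the second cluster (quartiles -0.0356 to 0.774), where the 29 genes had 0.803. However, the 29 were chosen in part on these arrays, and 3 of them, Cd14, Vcan and Cd68, are on that list. Dim members such as Clec4a1 (mean 3.41) and Cd163 (mean 3.44) can show little change. Among other bright members Lgals3 was at 0.91, Fcgr1a at 0.89 and Lyz2 at 0.66. Tlr2 was at 0.20, Cebpb at 0.06 and Ctsd at -0.38. Response to any other rat's serum is argued against by the same genes with allogeneic serum, at a median of -0.0736 within the second cluster (quartiles -0.217 to 0.158). The genes had a median of 0.798 with d60 DR+/+ serum within the second cluster and 0.145 with d40 PBS serum within the first (27 of 29 above 0), so nothing here ties the response to DRlyp/lyp serum in particular, but each of these medians used autologous arrays that had chosen the genes, and strain, age and diet of the donors stay open.

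The platelet genes were lower with d60 DR+/+ serum in 13 of 13 members within the second cluster, at a median of -0.944 (quartiles -1.28 to -0.846). Without DR+/+ replicate 4 the median was -0.639 (quartiles -0.827 to -0.424), so that array did not give the whole shift in the median. With the actin covariate the median was -0.869 (quartiles -1.13 to -0.638), so RNA integrity by actin did not either. These quartiles run over genes, not arrays. Array means of the list overlapped, from 8.65 to 10.00 with DR+/+ serum and 9.71 to 10.79 with autologous serum of the second cluster. Allogeneic arrays there ran from 8.87 to 10.73. Replicate 4 correlated with another array at 0.957 at most, while each other DR+/+ array reached at least 0.991. With this spread between arrays, a part played by either stays open. Fewer platelets in these cultures stay a candidate explanation. By limma 0 members differed from the list's own mean, but with 4 arrays on each side this could miss a difference. Abundant Pf4 was at -0.09, a deviation of 0.81 from that mean (limma adjusted p = 0.0633), and Treml1 deviated by -0.45 (limma adjusted p = 0.0633). Selp, at -0.02, had the largest deviation, 0.883. DRlyp/lyp serum gave -0.667 and IL-1B -0.0635, and a lower platelet RNA content caused by BB serum was not tested. PBMC isolation removes many platelets, and the amount that remains was not measured.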

How the results depend on the processing

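The fits with the cluster as a block, within clusters, with the actin covariate, with replicate numbers as a block in only the groups compared, with allogeneic serum of 1 cluster as reference and without DR+/+ replicate 4 beside the block were chosen after the data were seen. So was the allogeneic comparison without allogeneic replicates 2 and 3. For limits, 67 of 97 named genes were called, and over all alternatives their values and those of uncalled genes stayed on the same side of the threshold with the same sign in 2421 cases, became weaker in 477, stronger in 22 and reversed in 40. The 45 called lists stayed in 141 cases, became weaker in 105 and reversed in 24. Of the called genes 7 of 19 with DRlyp/lyp, 12 of 28 with DR+/+ and 15 of 20 with allogeneic serum kept their calls without each array, and 5, 8 and 0 under every alternative. Signal near background limits weakly expressed genes such as Il6, and 4 arrays per group limit small changes. Except where fewer probe sets, arrays or a stricter threshold explain a lower count, the cause was not tested. The IL-1B set could not be followed because it held 0 genes, and the lower DRlyp/lyp set held 1.

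Counts of called probe sets are given for d60 DRlyp/lyp serum (51 pooled), d60 DR+/+ serum (93) and allogeneic serum (12614), each against autologous serum. With only probe sets above the median of means they were 24, 59 and 6524. With array weights they were 14064, 7803 and 23124. Fitting only the groups of the comparison gave 17, 18 and 4171. An adjusted p under 0.2 with log2 of at least 0.5 gave 1430, 166 and 4859, and an adjusted p under 0.01 gave 16, 40 and 3471. The cluster as a block gave 9, 987 and 0, and the actin covariate 15, 38 and 1. Within the second cluster they were 11, 418 and 3, and within the first cluster 332 for allogeneic serum. The block without DR+/+ replicate 4 gave 863. A second quantile normalisation gave 6983 for allogeneic serum, while those for the d60 sera stayed within 1.5 times. With all allogeneic arrays as reference the d60 counts were 701 and 227, and with those of the second cluster 6683 and 7924. Without each array in turn they ran from 16 to 740, from 44 to 120 and from 7303 to 15654.

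With replicate numbers as a block, which pairs arrays by number, the counts were 9085, 3577 and 4824 for DRlyp/lyp, DR+/+ and allogeneic serum, and in a fit of the 2 groups alone 8478, 962 and 0. For IL-1B the replicate block gave 10094 and in the 2 groups alone 11021, where the unpaired fit called 0, and its residuals did not pair. The autologous arrays numbered 1 to 4 are all of the first cluster and the d60 and IL-1B arrays all of the second, so 8478, 962 and 11021 are contrasts of the clusters too, and the block over all groups sets the same arrays against each other. Array weights gave 15746 for IL-1B. The numbers did pair d60 DRlyp/lyp with DR+/+ serum, where the block gave 0 in both fits, d40 IL-1RA with PBS serum, where it gave 0 and 3 (Olfm1, Rasd1 at 0.74 with adjusted p = 0.0249 and 1 unnamed), and d40 PBS with autologous serum, where it gave 0 in both. The IL-1RA culture pair gave 0 in both.

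For comparisons with 0 calls pooled, array weights gave 15 for DRlyp/lyp against DR+/+ serum, 1 for d40 IL-1RA against PBS and 2 for d40 PBS against autologous serum. For d40 IL-1RA against PBS the cluster as a block and the fit within the array cluster each gave 1. With allogeneic serum as the reference d40 PBS serum gave 19030, and with allogeneic serum of the first cluster 8. Without each array it gave 0 to 1. IL-1RA in culture and the difference between the IL-1RA comparisons gave 0 under every alternative run.

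The 29 genes higher with d60 DRlyp/lyp serum had a median of -0.0121 in the d40 treatment comparison. It was 0.0179 with each array centred on its median, 0.152 when only the groups compared were fitted, -0.0575 with array weights, -0.0477 with the replicate block, 0.0851 for the set at adjusted p under 0.01 and 0.195 with the actin covariate, and -0.0740 to 0.0851 without each array. The set of genes higher with IL-1B held 4408 genes with array weights and 2955 with the replicate block, where IL-1B and cluster are mixed as in the counts above.

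For the genes, within the second cluster the allogeneic differences of Rrp12, Kel, Wasf2, Klf13 and Ubn1 turned to -0.399, -0.0953, 0.0168, 0.0571 and 0.245, and within the first that of Grm8 to -0.0282. Uncalled interleukin-1 genes changed sign. With IL-1B, Il1b was 0.107 after a second quantile normalisation, 0.217 with array weights, 0.105 with the block and 0.0261 with the actin covariate, Il1rn was -0.00943 with the block and -0.0493 within the second cluster, and Il1r2 was -0.0762 and -0.188. Il1rn was 0.0264 with the actin covariate in the d40 treatment comparison and 0.00817 with array weights in the difference between the IL-1RA comparisons. Without each array, Il1b ran from -0.271 to 0.232 with IL-1B and from -0.910 to 0.132 in the d40 treatment. Il1rn ran from -0.182 to 0.0920 with IL-1RA in culture, from -0.106 to 0.0690 in the d40 treatment and from -0.168 to 0.107 in the difference of both. Il1r2 ran from -0.365 to 0.223, from -0.415 to 1.02 and from -1.07 to 0.365 in these 3.

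For the lists, the cluster as a block and the fit within the cluster turned the medians of called lists. The cytokine list went to -0.0356 and -0.0363 for DRlyp/lyp, -0.121 and -0.134 for DR+/+, -0.0676 and -0.0939 for IL-1B and 0.0048 and 0.0182 for d40 PBS serum. T-cell genes went to 0.216 and 0.137 for DRlyp/lyp, to 0.0155 for DR+/+ and 0.0134 for IL-1B with the block, and stood at -0.0702 and -0.0603 within the cluster while the test pointed up. Erythroid genes went to -0.195 and -0.239 for DR+/+ and 0.0148 and 0.0282 for d40 PBS serum, and within the cluster to -0.0169 for DRlyp/lyp and -0.0376 for IL-1B. Within the cluster, apoptosis genes were at 0.0204 for DRlyp/lyp and at 0.0219 for d40 PBS serum, where the test pointed down, and cell cycle genes at -0.105 for DR+/+. Glucocorticoid targets were at 0.0144 for DRlyp/lyp with the replicate block.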

Other observations

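The IL-1B set of 100 genes, the sets of called genes within a cluster and the named genes here were chosen after the values were seen. Within the second cluster the genes below passed with d60 DR+/+ serum, of which Klf4 and Mmp14 had also passed in the pooled arrays, although regrouping the arrays did not exclude chance for that count of 418 (2 of 35 splits, highest other 2379). The early gene Fos was higher by log2 1.97 (limma adjusted p = 0.0412), the transcription factor Klf4 by 1.78 (limma adjusted p = 0.000803), the transcriptional repressor Spen by 1.75, the matrix protease Mmp14 by 1.65, Mdfic by 1.52 and the transcription factor subunit Taf4 by 1.45. Lower were Arhgap28 at -1.59, the insulin-responsive glucose transporter Slc2a4 at -1.53, the potassium channel subunit Kcnab1 at -1.53, Dennd2c at -1.51, the ATP receptor P2rx1 at -1.46, cyclooxygenase Ptgs1 at -1.42, the thrombin receptor subunit F2rl2 at -1.35, Cd151 at -1.32, the actin-severing Gsn at -1.31 and biglycan, Bgn, at -1.30. Immediate early genes, which include Fos and Klf4, had 4 of 23 members up there (5 adjusted over the list alone, median 0.19, adjusted p = 0.00169, and adjusted p = 0.0637 with an estimated correlation).

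With d60 DRlyp/lyp serum plus IL-1RA, 17 probe sets differed from autologous serum within the second cluster, 16 of them higher. They covered 8 genes, Akr1b8 at 2.82, Vcan at 2.05, Ccl2 at 2.02, Nqo1 at 1.81, Mmp14 at 1.63, Dab2 at 1.18, the sterol exporter Abcg1 at 1.16 and Ccdc71 at 0.92. The 53 genes higher with d60 DR+/+ serum had a median of 0.03 between DRlyp/lyp serum with and without IL-1RA (p = 0.705 by camera with an estimated correlation).

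The 100 genes with the highest statistic for IL-1B within the second cluster, none of which passed the test singly, were followed into the comparisons that share no array with it. Between DRlyp/lyp and DR+/+ serum their median was -0.41, with 6 of 100 above 0 (camera p = 5.0e-26, p = 0.0375 with an estimated correlation, fry p = 0.10). Between DRlyp/lyp serum with and without IL-1RA it was 0.30, with 91 above 0 (p = 0.0667 with an estimated correlation, fry p = 0.222), and in the d40 treatment comparison 0.01 with 57 above 0 (p = 0.586 with an estimated correlation). With 0 of these genes called for IL-1B, and 1121 probe sets at an unadjusted p under 0.05 where chance gives 1552, the set is not shown to respond to IL-1B.

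Genes called with d60 DR+/+ serum within the second cluster were followed into the d40 PBS comparison with autologous serum within the first cluster. They come from the fit with 418 calls, for which regrouping did not exclude chance. The 69 lower genes had a median of -0.07 with 24 above 0 (camera p = 1.77e-07, p = 0.183 with an estimated correlation, fry p = 0.521). The 153 higher had one of 0.03 with 86 above 0 (camera p = 0.850 with an estimated correlation).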
